A study of Streptococcus sanguinis with 32 samples.

How the data were processed

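RNA was sequenced from whole cells of Streptococcus sanguinis SK36, an oral commensal streptococcus, grown for 18 h at 37 °C in a chemically defined medium with 1.7% sucrose or 3.4% glucose, under oxic or anoxic gas, per the labels' protocols. Some cultures also held Corynebacterium durum, Filifactor alocis or Porphyromonas gingivalis W83, or 15 mL of filtered P. gingivalis culture medium. The 32 libraries fall into 14 groups, of which the 4 oxic groups hold 3 libraries each and the 10 anoxic groups hold 2. Replicate numbers were taken from the titles, and the anoxic groups hold only the numbers 2 and 3. No label says that replicates came from separate starter cultures, so p-values measure the spread between these libraries, which may be technical in part.

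The libraries were made with a stranded kit that includes a ribosomal RNA depletion step, per the labels' protocols. The submitters' processing notes name cutadapt 2.10, BWA, SAMtools, HTSeq and DESeq2, without parameters. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. The deposited count files hold whole-number read counts for 2270 locus tags and 5 HTSeq summary rows per library. Those summary rows were kept out of library sizes and tests, and reads outside any counted feature made up 95.6% to 97.9% of the listed reads (median 96.8%). The deposited normalized signal tables (3 tables, 24 libraries between them) equal the read counts divided by a constant per library, checked tag by tag, and were used only to see which libraries the authors had scaled together. A further deposited table gives, per library, a value named Count and 1023 columns per gene. Its gene columns were not used. The unit of Count and the object counted are not stated in the labels or the file.

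The tags could not be given gene names. The reference table used here describes another strain of the species (2256 genes), it matched 0 of the 2270 tags, and the files do not pair tags with names. Tags are therefore reported as deposited, at most 2 that rose and 2 that fell per comparison. For the same reason 23 gene lists and a panel of named genes that had been fixed before the data were examined were not tested, and ribosomal and transfer RNA tags could not be removed as an alternative. Tags that share reads with near-identical or overlapping genes could not be recognised.

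Counts were tested with edgeR 4.0.16 in R 4.3.3. One quasi-likelihood model (robust) was fitted over all 32 libraries with a mean per group, TMM normalization and edgeR's filter on low counts, which kept 1465 tags. It left 18 residual degrees of freedom, and the common biological coefficient of variation was 0.424. Adjusted p-values are Benjamini-Hochberg values over the 1465 tags, with a threshold of 0.05, and a standard error is the log2 fold change divided by the square root of F. CPM values are counts per 1e6 reads assigned to tags, scaled by TMM. The model, the 15 comparisons between groups and the 5 differences between effects were fixed before the data were examined. After the data were seen, 8 averages were added, each the mean of the same contrast over all backgrounds in which it can be made. The naming rule fixed beforehand required an adjusted p under 0.05, a mean of at least 10 CPM in the higher group, replicates that do not overlap and at most 2 tags from a run of neighbouring tag numbers (gaps of up to 3), in order of fold change. For averages the condition on replicates was replaced by the same direction in every background. An average with 5 or fewer called tags has them all named. The limit of 2 named tags in each direction is smaller than the limit fixed beforehand.

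On simulated counts with the real means, library sizes and tagwise dispersions and 200 changed tags of the 1465, the same steps recovered, for sucrose against glucose in oxic culture, 7.67% of 2-fold and 55.3% of 4-fold changes. For anoxic against oxic glucose culture these shares were 1.67% and 40.0%, and for sucrose against glucose in anoxic culture 2.00% and 27.3%. For the averages they were 54.3% and 96.3% for sugar, 53.7% and 96.7% for atmosphere, 78.3% and 99.0% for C. durum, and 18.0% and 73.7% for F. alocis. Each simulated change had the same size in every background, and same-numbered libraries shared nothing. The shares for averages therefore do not cover effects that vary between backgrounds. False calls made up 0.794% to 8.33% of the calls.

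Replicates of a group were compared first. No 2 libraries were identical, and the chi-square per degree of freedom between replicates was 8.57 to 115, far above sampling noise. Pearson's r of log2 CPM between replicates, across tags, was 0.79 to 0.96. The deviations of each library from its group mean were then correlated between same-numbered libraries of the groups compared. The numbers were taken to pair libraries where at least 3 pairs all had r over 0.1. This held for C. durum in oxic glucose (r 0.20 to 0.75) and oxic sucrose (0.19 to 0.30), and for its average over backgrounds (16 pairs, 0.17 to 0.75). By number of pairs it also held for the averages of F. alocis (4 pairs, 0.19 to 0.27), P. gingivalis (0.17 to 0.19) and its supernatant (0.11 to 0.22). The same went for cells against supernatant (0.35 to 0.51) and F. alocis against P. gingivalis (0.27 to 0.37). In a group of 2 libraries, however, the deviations mirror each other, so both pairs of 2 such groups give the same r. These last 5 averages therefore hold 2 distinct values each, short of the minimum of 3. Some of the 16 C. durum pairs repeat in the same way. The pairing comes from these correlations alone, since no label says what a number stands for. A fit with the replicate number as a block is the paired alternative throughout.

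Count was compared on the log2 scale by exact permutation tests that reassign cultures within each background, two-sided, with Benjamini-Hochberg adjustment over the 8 comparisons. These tests were chosen after the data were seen. Python 3.11.15 with NumPy 2.4.6 was used.

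Alternatives fixed beforehand were DESeq2 size factors in place of TMM, the Wald test of DESeq2 1.42.0 on the same groups, no filter on low counts, the replicate block, a fit to the libraries of the compared groups only, and leaving out each library in turn. Alternatives added later left out the most abundant tag, the libraries numbered 1 or the F. alocis libraries numbered 2. Others ran DESeq2 within the libraries of 1 deposited table, or gave C. durum a block per background and number. For the atmosphere average, leaving out the libraries numbered 1 was also combined with the replicate block.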

Results

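The series asks how sugar, oxygen and other oral bacteria affect S. sanguinis in late log phase, under a title on membrane vesicle formation. Reads assigned to tags numbered 143258 to 586357 per library, with a median of 334080, out of 6470030 to 15510500 listed reads. A median of 3.00% of the listed reads were assigned. The median count per tested tag was 9 to 35 per library, so most tags were measured with few reads. A single tag, SSA_2207, held 16.4% to 58.0% of the assigned reads of a library, and SSA_0350 held 3.05% to 7.14%. In oxic cultures the share of SSA_2207 was 16.4% to 22.1% in the 4 libraries numbered 1, 23.6% to 33.5% in those numbered 2 and 33.6% to 54.8% in those numbered 3. The first 3 principal components of log2 CPM held 27.0%, 16.3% and 8.47% of the variance.

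**Figure D1:**
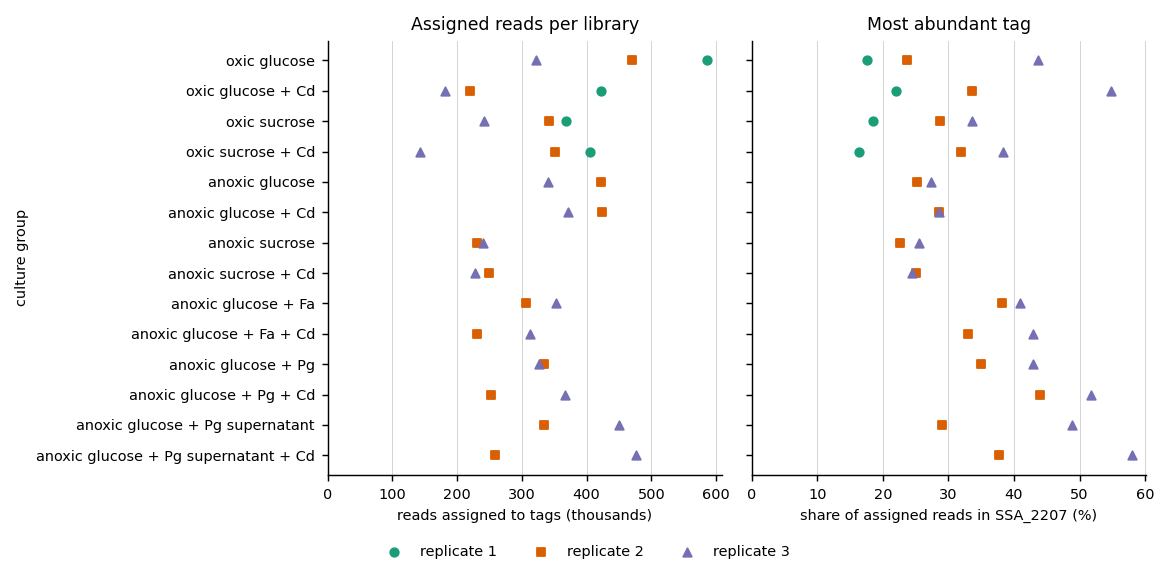
Reads assigned to tags (left) and share of those reads in tag SSA_2207 (right, percent), 1 point per library, by culture group; Cd, Fa and Pg stand for C. durum, F. alocis and P. gingivalis. Depth ran from 143258 to 586357 reads, and the SSA_2207 share from 16.4% to 58.0%.

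Sucrose was used at 1.7% and glucose at 3.4% throughout, so the kind of sugar and its concentration cannot be told apart. The deposited Count of a culture was far lower in sucrose than in glucose. Its unit and object are not stated, so only ratios between cultures are compared, and these assume a scale with a true zero. In oxic culture Count was 6.10 ± 5.94 in sucrose and 61.3 ± 20.4 in glucose (mean ± SD, n = 2 each), and with C. durum it was 6.31 ± 1.71 and 54.4 ± 17.1. In anoxic culture it was 13.2 ± 15.2 in sucrose and 48.6 ± 21.7 in glucose, and with C. durum 13.1 ± 15.4 and 70.6 ± 3.60. Over these 4 backgrounds the geometric mean was 9.04-fold lower in sucrose, in 8 of 8 same-numbered pairs (exact permutation test, p = 0.00154, the smallest the test can give; adjusted p = 0.0123). The ratio was 17.0-fold among cultures numbered 2 and 4.79-fold among those numbered 3. With sign flips of the pairs, a replicate block, the exact p was 0.00781, the smallest that 8 pairs can give, and the adjusted p was 0.0625, so this test could not pass beside the other 7 comparisons.

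Count was also low with P. gingivalis. In anoxic glucose it was 21.7 ± 2.21 with P. gingivalis cells and 6.52 ± 5.88 with P. gingivalis and C. durum (n = 2 each). Against the cultures without P. gingivalis it was 5.47-fold lower on average (2.13-fold without and 14.1-fold with C. durum), in 4 of 4 pairs, with an exact permutation p of 0.0556, the smallest possible here, and an adjusted p of 0.111. With the supernatant Count was 27.3 in 1 culture and 12.95 in both cultures with C. durum, 3.03-fold lower on average (exact permutation test, p = 0.111, adjusted p = 0.178). That ratio was 1.69-fold without and 5.45-fold with C. durum, so it becomes 5.45-fold when the single culture without C. durum (numbered 2) is left out. With F. alocis it was 52.0 ± 0.615 without and 55.9 ± 3.52 with C. durum, 1.06-fold lower than without F. alocis (exact permutation test, p = 0.833). Atmosphere changed Count by 1.21-fold (higher in anoxic culture, 5 of 8 pairs, exact permutation test, p = 0.668), and C. durum by 0.801-fold over 7 backgrounds (lower in 7 of 13 pairs and higher in 5, exact permutation test, p = 0.439). Neither average could be told from the spread between cultures. The C. durum average joins backgrounds without overlap that moved in opposite directions, such as 1.53-fold in anoxic glucose and 0.232-fold with P. gingivalis. For atmosphere the cultures overlapped except in glucose with C. durum, where all anoxic ones lay higher, at a ratio of 1.33.

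**Figure D2:**
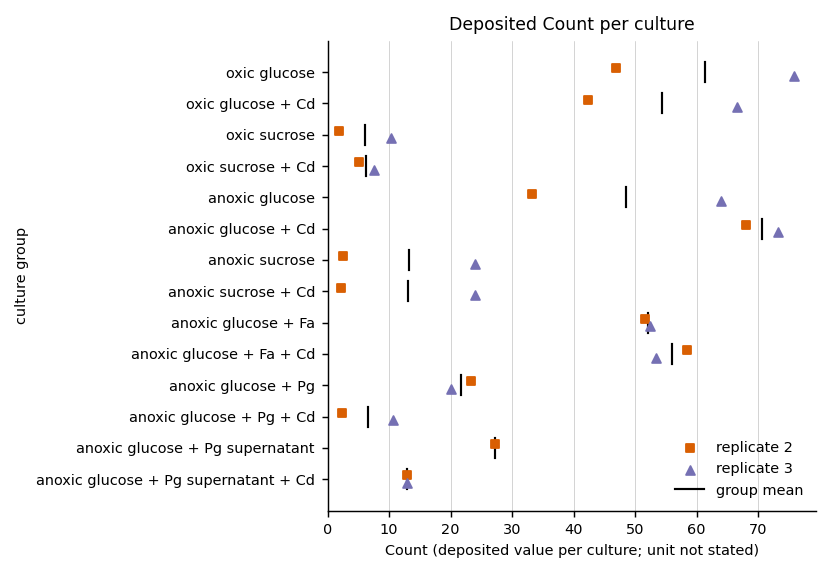
Deposited Count per culture (horizontal axis, unit not stated) by culture group, with 1 point per culture and a bar at the group mean; libraries numbered 1 and 1 supernatant culture have no value. The sucrose cultures sit between 1.9 and 24, and the glucose cultures without P. gingivalis cells or supernatant between 33.2 and 75.76.

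Sucrose against glucose asked which transcripts differ between cultures with 1.7% sucrose and 3.4% glucose. The kind of sugar and its concentration cannot be told apart here. SSA_2022 and SSA_1367 were the leading tags that rose in sucrose, and SSA_1056 and SSA_1369 the leading tags that fell. Averaged over 4 backgrounds, SSA_2022 rose by 2.69 on the log2 scale (SE 0.43, edgeR adjusted p = 0.00156). Without oxic glucose with C. durum numbered 1 it rose by 3.43. That group then has 0 counts, so this fold depends on a prior count. SSA_2022 had 0 to 4 counts per library in the glucose groups compared, and DESeq2 gave it no adjusted p. Its level was 60.7 ± 35.1 CPM in oxic sucrose and 6.31 ± 4.11 CPM in oxic glucose (SD, n = 3), and 34.1 ± 19.4 and 8.28 ± 2.47 CPM in anoxic culture (n = 2). SSA_1367 is far more abundant, with 27332 ± 6374 CPM in oxic sucrose against 4746 ± 1775 CPM in oxic glucose, and rose by 1.94 (SE 0.36, edgeR adjusted p = 0.00473). SSA_1369 fell by 1.11 on the log2 scale (SE 0.23, edgeR adjusted p = 0.00570), from 1554 ± 437 CPM in oxic glucose to 777 ± 256 CPM in oxic sucrose. SSA_1056 fell by 1.49 on the log2 scale (SE 0.39, edgeR adjusted p = 0.0396), from 32.1 ± 7.91 to 15.1 ± 3.24 CPM. SSA_1056 lost its call in 14 of 20 fits with 1 library left out, with a log2 fold change of at most -1.28. The value was -2.53 without anoxic sucrose with C. durum numbered 2. That group then has 0 counts, so this fold depends on a prior count. The call was kept without oxic sucrose numbered 3, oxic sucrose with C. durum numbered 2 or 3 or oxic glucose numbered 2. It was also kept without oxic glucose with C. durum numbered 1 or anoxic sucrose with C. durum numbered 2. SSA_1369 lost its call without anoxic sucrose numbered 2, anoxic sucrose with C. durum numbered 3 or anoxic glucose numbered 3. The average called 32 tags, 23 higher and 9 lower in sucrose, and 23 of the 32 changed at least 2-fold. The split was even in other fits, with 38 higher and 39 lower with the replicate block and 36 higher and 37 lower with DESeq2. Within a single background edgeR called 0 tags, in oxic culture with 105 at an unadjusted p under 0.05 and 4 by DESeq2, and in anoxic culture with 66 and 0. Chance would give 73 unadjusted. DESeq2 called 73 tags for the average, and edgeR called 7 to 43 with 1 library left out, the fewest without anoxic sucrose numbered 2.

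**Figure D3:**
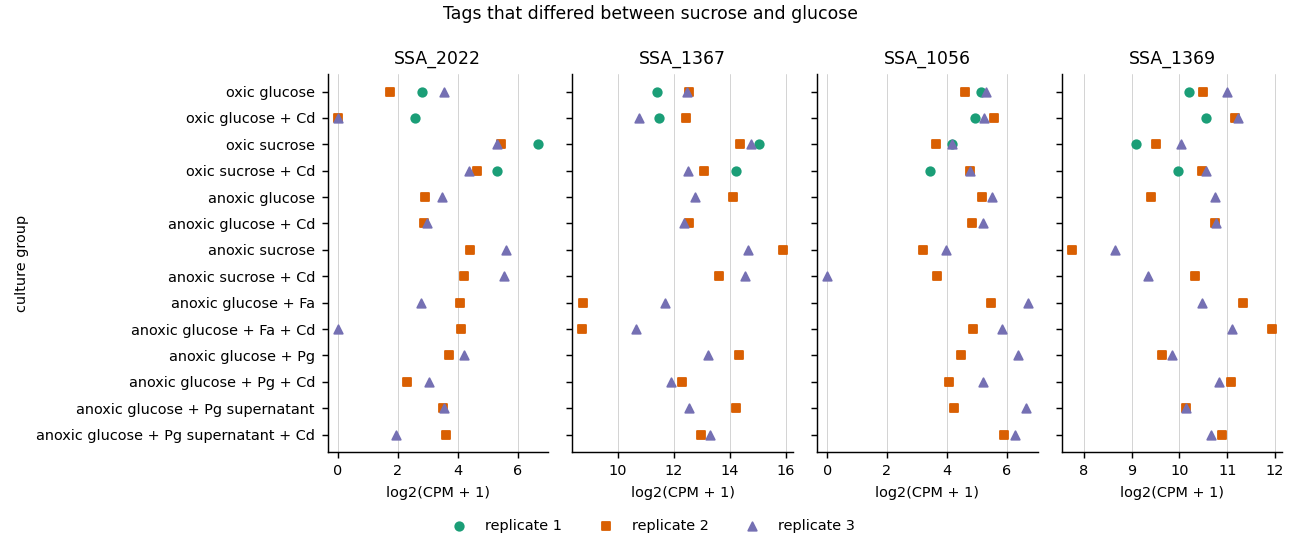
Level of 4 tags in log2(CPM + 1), 1 point per library, by culture group; Cd, Fa and Pg stand for C. durum, F. alocis and P. gingivalis. SSA_2022 averaged 60.7 CPM in oxic sucrose and 6.31 CPM in oxic glucose, and SSA_1369 averaged 777 and 1554 CPM.

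Atmosphere gave the longest list of tags among the averages in the fit without a block. SSA_0312 fell by 2.45 on the log2 scale in anoxic culture (SE 0.36, edgeR adjusted p = 0.000153), lower in 4 of 4 backgrounds. It averaged 4109 ± 2589 CPM in oxic and 345 ± 139 CPM in anoxic sucrose, and 2638 ± 2024 and 617 ± 142 CPM in glucose. SSA_0034 fell by 2.34 on the log2 scale (SE 0.55, edgeR adjusted p = 0.00471), from 40.1 ± 22.3 to 3.68 ± 5.20 CPM in sucrose, the latter from counts of 0 and 2. Without anoxic sucrose numbered 3 the log2 fold change of SSA_0034 was -3.21. The library left in that group had 0 counts, so this fold depends on a prior count. SSA_0004 rose by 2.49 (SE 0.38, edgeR adjusted p = 0.000153), from 23.7 ± 2.33 CPM in oxic to 118 ± 99.1 CPM in anoxic glucose. SSA_1833 was called as well (edgeR adjusted p = 0.000489), with 5.84 ± 7.28 CPM in oxic and 26.7 ± 2.31 CPM in anoxic glucose. In sucrose it averaged 5.19 ± 0.80 CPM in oxic and 16.5 ± 23.4 CPM in anoxic culture, the latter from counts of 0 and 9. It had 0 counts in all 3 libraries of oxic glucose with C. durum, so the fitted fold of the average depends on a prior count and is not given. Over 4 backgrounds 273 tags were called, 127 higher and 146 lower in anoxic culture, and 149 of them changed at least 2-fold. Without the anoxic libraries numbered 3 of sucrose, sucrose with C. durum, glucose or glucose with C. durum, each left out alone, the count was 153, 152, 158 and 158. SSA_1833 lost its call without that of sucrose. In single backgrounds edgeR called 0 tags. In glucose 153 had an unadjusted p under 0.05 and DESeq2 called 21, and in sucrose 214 had an unadjusted p under 0.05 and DESeq2 called 59. All libraries numbered 1 are oxic, and without them 348 tags were called, 217 higher and 131 lower. No label gives a batch, so any difference in handling between oxic and anoxic cultures cannot be told apart from the atmosphere.

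**Figure D4:**
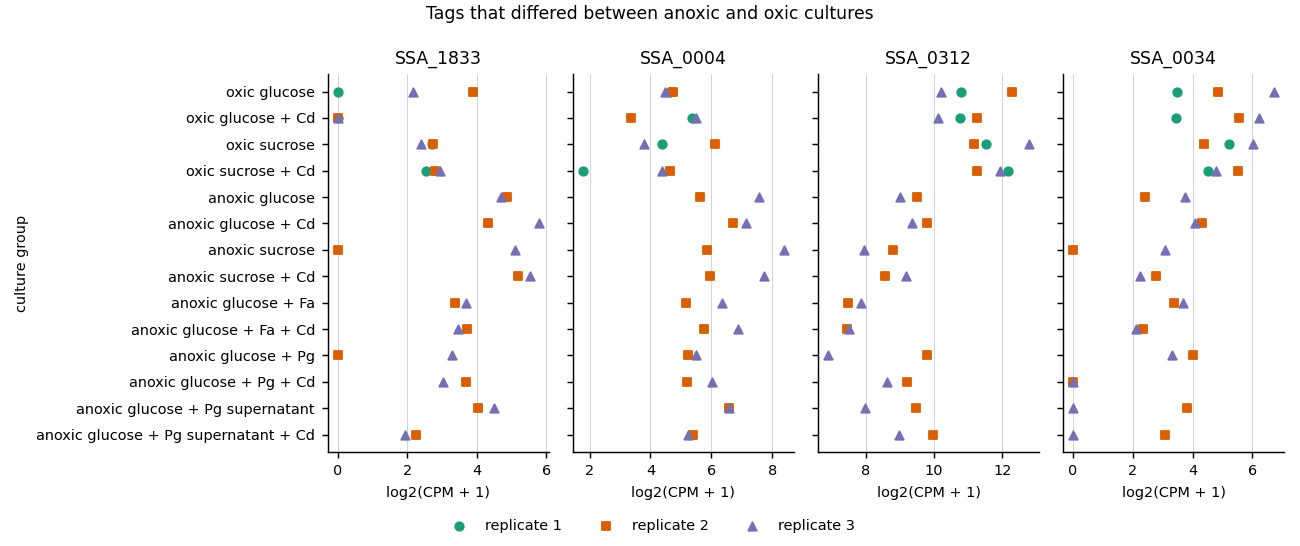
Level of 4 tags in log2(CPM + 1), 1 point per library, by culture group; Cd, Fa and Pg stand for C. durum, F. alocis and P. gingivalis. SSA_0312 averaged 4109 CPM in oxic sucrose and 345 CPM in anoxic sucrose, and SSA_1833 had 0 counts in oxic glucose with C. durum.

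C. durum is an oral corynebacterium, and tag levels with and without it could be compared in 7 backgrounds. Whether reads of partner cells were counted in S. sanguinis tags was not tested, here or for the other partners. SSA_1366 and SSA_1365, neighbours by tag number, rose with C. durum in 7 of 7 backgrounds, on average by 0.96 (SE 0.21) and 0.93 (SE 0.19) on the log2 scale (edgeR adjusted p = 0.0262 for both). In anoxic sucrose SSA_1365 averaged 154 ± 21.9 CPM alone and 642 ± 466 CPM with C. durum, and in oxic glucose 993 ± 316 and 1149 ± 362 CPM. SSA_0170 fell by 1.66 on the log2 scale (SE 0.35, edgeR adjusted p = 0.0262), from 40.1 ± 8.86 to 6.03 ± 6.08 CPM in oxic sucrose. SSA_0654 fell by 1.34 on the log2 scale (SE 0.32, edgeR adjusted p = 0.0457), with 1 to 13 counts per library outside the libraries at 0, and lost its call in 22 of 32 fits with 1 library left out. Its log2 fold change was -2.01 without P. gingivalis with C. durum numbered 3. SSA_0654 then had 0 counts in that group, so this fold depends on a prior count. It kept the call only without oxic sucrose numbered 1 or 3, oxic sucrose with C. durum numbered 1, oxic glucose numbered 3, oxic glucose with C. durum numbered 1, anoxic sucrose with C. durum numbered 3, F. alocis or P. gingivalis numbered 2, or either of these with C. durum numbered 3. The average called 8 tags, 5 higher and 3 lower. DESeq2 called 113 tags, among them 5 of the 8, and gave SSA_0170 and SSA_0654 no adjusted p. With the replicate block the average called 121 tags, 60 higher and 61 lower, among them all 8. With a block per background and number it called 368, 153 higher and 215 lower. Libraries were left out 1 at a time only for the average without a block. It called 0 tags without any 1 of 11 libraries, namely those of anoxic sucrose numbered 2 (alone and with C. durum), anoxic glucose numbered 2, anoxic glucose with C. durum numbered 2 and 3, F. alocis numbered 3, P. gingivalis numbered 3, supernatant numbered 3, and the libraries of these 3 with C. durum numbered 2. In the single backgrounds edgeR called 0 tags. The counts at an unadjusted p under 0.05 were 41 in oxic glucose, 36 in oxic sucrose, 36 in anoxic glucose and 35 in anoxic sucrose, below the 73 that chance gives, and DESeq2 called 0 in each. The median half-width of the 95% interval of a log2 fold change was 1.17 in oxic glucose and 0.51 for the average, so 0 calls in a single background do not show that the effect there is small.

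**Figure D5:**
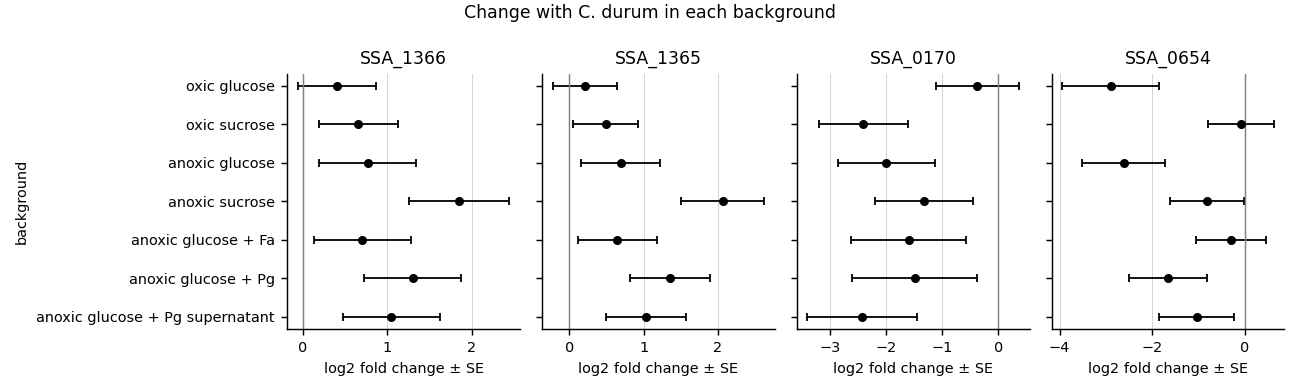
Log2 fold change with C. durum for 4 tags (points) with its standard error (bars) in each of 7 backgrounds; Fa and Pg stand for F. alocis and P. gingivalis. SSA_1366 and SSA_1365 lie above 0 and SSA_0170 and SSA_0654 below 0 in all 7.

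F. alocis, an anaerobe found in the oral cavity, was added in anoxic glucose. Averaged over cultures without and with C. durum, SSA_1888 rose by 2.93 (SE 0.59) and SSA_0648 by 2.64 (SE 0.60) on the log2 scale, while SSA_1299 fell by 2.85 (SE 0.73) and SSA_1367 fell by 2.59 (SE 0.57). The edgeR adjusted p was 0.0317 for SSA_1888, SSA_0648 and SSA_1367, and 0.0494 for SSA_1299. SSA_1888 averaged 223 ± 257 CPM with F. alocis and 27.5 ± 10.5 CPM without (n = 2), where the SD with F. alocis exceeds the mean. SSA_1367 averaged 1876 ± 2040 CPM with and 12328 ± 7623 CPM without F. alocis. With the replicate block the average called 60 tags, 28 higher and 32 lower, and with DESeq2 77 tags, 39 higher and 38 lower. In the fit without a block it called 18 tags, 12 higher and 6 lower. It called 0 tags without any 1 of 6 libraries, the F. alocis libraries numbered 2 (alone and with C. durum) and the 4 control libraries of anoxic glucose (alone and with C. durum). SSA_1299 lost its call whichever of the 8 libraries was left out. The F. alocis libraries numbered 2 stand apart from all others on the third principal component (-27.0 and -30.4, against -5.31 to 8.10). Their SSA_0648 levels were 581 and 497 CPM, and those of the libraries numbered 3 were 35.5 and 66.6 CPM. Without the library numbered 2 of F. alocis alone the log2 fold change was 1.09 for SSA_0648 and 1.72 for SSA_1888, and without that with C. durum it was 1.61 and 1.77. Without both it was 0.054 for SSA_0648, 0.56 for SSA_1888 and -1.85 for SSA_1367. That of SSA_1367 was -3.65 without F. alocis numbered 3 and -3.21 without F. alocis with C. durum numbered 3. A fit to the 4 groups compared called 0 tags. With DESeq2 size factors the split was 13 higher and 2 lower. For F. alocis against S. sanguinis alone edgeR called 0 tags (96 at an unadjusted p under 0.05, 5 by DESeq2), and for F. alocis added to the C. durum coculture also 0 (122 and 1).

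P. gingivalis, a Gram-negative anaerobe linked with periodontitis, gave 3 called tags over both backgrounds, and all 3 lie close together by tag number. SSA_0370 rose by 2.63 (SE 0.49, edgeR adjusted p = 0.00829), SSA_0371 rose by 2.53 (SE 0.47, edgeR adjusted p = 0.00829) and SSA_0367 fell by 2.76 on the log2 scale (SE 0.59, edgeR adjusted p = 0.0324). SSA_0371 averaged 52.9 ± 14.6 CPM alone and 476 ± 252 CPM with P. gingivalis, and 144 ± 8.86 and 545 ± 117 CPM in the presence of C. durum. SSA_0367 averaged 4114 ± 2.98 CPM alone and 658 ± 6.74 CPM with P. gingivalis (n = 2). These changes were also seen with F. alocis, against the same control libraries. In the F. alocis average SSA_0370 rose by 2.33, SSA_0371 rose by 2.20 and SSA_0367 fell by 2.23 on the log2 scale, and all 3 were called there too. For P. gingivalis the average called 0 tags without anoxic glucose numbered 3, anoxic glucose with C. durum numbered 2 or 3, or P. gingivalis numbered 2, and 1 tag without anoxic glucose numbered 2. SSA_0367 lost its call whichever of the 8 libraries was left out, with a log2 fold change of -2.92 to -2.54. With supernatant SSA_0371 averaged 192 ± 39.8 CPM and SSA_0367 1753 ± 241 CPM, and with supernatant and C. durum 391 ± 0.669 and 699 ± 203 CPM (2259 ± 823 CPM for SSA_0367 with C. durum alone). With the replicate block 41 tags were called for cells, 16 higher and 25 lower, and a fit to the compared groups alone called 159. For the supernatant edgeR called 0 tags on average (223 at an unadjusted p under 0.05, 0 by DESeq2, 118 in a fit to the compared groups alone). Cells and supernatant were not separated either, with 0 tags on average, 11 at an unadjusted p under 0.05 and 0 by DESeq2. In single backgrounds edgeR called 0 tags. Against S. sanguinis alone the unadjusted counts were 95 for cells (2 by DESeq2) and 35 for supernatant (0 by DESeq2), and against the C. durum coculture 121 and 151 (0 by DESeq2 in both). Cells against supernatant gave 12 unadjusted and 0 by DESeq2. The F. alocis, P. gingivalis and supernatant comparisons share the same control libraries, so their fold changes are not independent. The supernatant was made in a rich medium, and no library with that medium alone was analysed here.

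F. alocis and P. gingivalis cultures were compared directly, which avoids the shared controls. SSA_1367 and SSA_1362 fell by 2.56 (SE 0.57) and fell by 2.44 (SE 0.56) on the log2 scale with F. alocis relative to P. gingivalis (edgeR adjusted p = 0.0307 and 0.0358). SSA_1362 averaged 58.3 ± 51.3 CPM with F. alocis and 615 ± 282 CPM with P. gingivalis, and 60.1 ± 56.2 and 173 ± 38.5 CPM in the presence of C. durum. Without F. alocis numbered 3 the log2 fold changes of SSA_1367 and SSA_1362 were -3.62 and -3.14. Without F. alocis with C. durum numbered 3 they were -3.18 and -3.23. They were smaller without F. alocis numbered 2 (-2.15 and -2.10) or F. alocis with C. durum numbered 2 (-2.24 and -2.09). Without both of these they were -1.82 and -1.745. SSA_2029 and SSA_0228 were higher with F. alocis (edgeR adjusted p = 0.0469 for both), but each had 0 counts in both libraries of 1 P. gingivalis group, so the fitted folds are not given. The average called 22 tags, 15 higher and 7 lower. It called 0 without any 1 of 6 libraries, the F. alocis libraries numbered 2 (alone and with C. durum) and the 4 P. gingivalis libraries, and 0 in a fit to the compared groups alone.

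Whether an effect differed between settings was tested directly 5 times, and edgeR called 0 tags in each. For the sugar effect in anoxic minus oxic culture 28 tags had an unadjusted p under 0.05. The other counts were 25 for the C. durum effect in sucrose minus glucose, 30 for the C. durum effect in anoxic minus oxic glucose, 19 for F. alocis with minus without C. durum, and 15 for P. gingivalis with minus without C. durum. DESeq2 called 0 in all 5. The leading tag of the second of these, SSA_0401, had a log2 difference of 3.44 (SE 0.95) with an edgeR adjusted p of 1.00. The median half-width of the 95% interval was 1.64 to 1.98 on the log2 scale, before any adjustment over tags, so 0 calls leave large differences between effects possible.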

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

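The tests of partner reads, of the libraries numbered 1 and of placement along tag numbers, and all tests of Count, were chosen after the values they measure had been seen; no group holds the 4 libraries that a test for a stray sample needs.

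In every library most reads lay outside the counted features, with a median of 96.8%, a signal in data that no comparison uses. Reads of the partner bacteria are argued against as the main source, since the share was at least 95.6% in S. sanguinis grown alone. Whether partner reads were also counted in the tags was not tested. Ribosomal RNA left after depletion stays open, because 0 tags could be matched to an annotation. Reads counted on the opposite strand also stay open, because the kit marks strand and 0 labels give the strand setting of the counting. If that were the cause, the tag counts would measure antisense reads, so it bears on each tag named here; no biological explanation was tested.

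Count with C. durum differed in direction between backgrounds, but no test of a difference passed 0.05. All cultures with C. durum lay above those without in anoxic glucose, at a ratio of 1.53, and with F. alocis, at 1.07. All lay below those without where P. gingivalis cells were present, at 0.232, and with the supernatant, at 0.475 (1 culture without C. durum). In the other 3 backgrounds the cultures overlapped, at 0.890 in oxic glucose, 1.40 in oxic sucrose and 0.938 in anoxic sucrose. For anoxic glucose against P. gingivalis, a contrast picked after the values were seen, the effects differed 6.60-fold (exact permutation test within backgrounds, p = 0.0556, the smallest possible with 36 arrangements). For anoxic glucose against F. alocis they differed 1.43-fold (exact permutation test, p = 0.556). For the supernatant the difference was not tested.

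Same-numbered libraries of oxic glucose with and without C. durum deviated from their group means together, with r of 0.755, 0.198 and 0.661 across tags. Depth is argued against as the whole cause, since r stayed at 0.421 and 0.354 after regression on log depth for the pairs numbered 1 and 3. For these pairs it fell, however, from 0.755 and 0.661. The lowest r of the 3 pairs, 0.231 for that numbered 2, bears little on depth. The depth deviations of that pair were small and opposite in sign (0.075 and -0.22 on the log2 scale). The share of SSA_2207 is argued against as the whole cause too, with a lowest r of 0.145, although r fell from 0.661 to 0.145 for the pair numbered 3. A shared culture or library day stays open, because 0 labels name one.

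The 273 tags of the atmosphere average are weighed against technical explanations. Libraries numbered 1 are argued against, since 208 of the 273 tags were called again without them. The share of SSA_2207 (268 of 273 called again with it as a covariate) and depth (270 of 273) are argued against as well. Separate handling of oxic and anoxic cultures cannot be told apart from the atmosphere, as 0 labels name a batch. The effect of oxygen itself, which the design names, stays open beside it.

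Other splits of the libraries were counted for each result with groups of 3 or more. For the sugar average 1 of 100 splits within backgrounds, the real one, gave as many as 32 tags, with 0 in the highest other. For atmosphere 1 of 100 gave 273, with 129 in the highest other, and for C. durum 1 of 100 swaps within same-numbered pairs gave 8 (121 with the replicate block), with 0 in the highest other in both fits. For these 3 averages no other split drawn gave as many tags. The split that gave 129 tags had only oxic libraries on 1 side in each background except sucrose with C. durum. It thus kept much of the difference between oxic and anoxic cultures, so 129 is not a chance level. A share of 1 in 100 is the smallest these draws can give, and the averages were chosen after the data were seen. Chance is therefore not excluded. The averages of F. alocis (real 18, highest other 5, 1 of 18 as many), P. gingivalis (3, 0, 1 of 18), its supernatant (0, 0, 18 of 18), cells against supernatant (0, 13, 18 of 18) and F. alocis against P. gingivalis (22, 88, 2 of 18) have too few splits for a share under 0.05. The split that gave 88 tags parts the libraries numbered 2 from those numbered 3, as does the one that gave 13, and neither parts a same-numbered pair; with the replicate block F. alocis against P. gingivalis gave 26 tags and the highest other split 1. The single oxic comparisons have 10 splits each, also too few, with 0 tags in all 10 for sugar and for C. durum in sucrose. For C. durum in oxic glucose (real 0, as many in 10 of 10) the highest other split gave 372 tags, with both libraries numbered 1 and the culture alone numbered 2 on one side. These are the 3 deepest of the 6 libraries, with the lowest shares of SSA_2207, and what caused the split was not tested. For the C. durum effect in sucrose minus glucose, 100 of 100 splits gave at least the real 0, with 430 in the highest. Where the real count is 0 every split reaches it, so these shares say nothing about chance.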

How the results depend on the processing

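The averages, the Count comparisons and 5 alternatives were chosen after the data were seen. For the planned comparisons a count of 0 tags became, with DESeq2, 4 for sugar in oxic culture, 21 for atmosphere in glucose, 59 for atmosphere in sucrose, 5 for F. alocis, 2 for P. gingivalis and 1 for F. alocis added to C. durum. With the replicate block it became 6 for atmosphere in glucose and 49 in sucrose, though same-numbered libraries did not pair there (r 0.07 to 0.13 and -0.19 to -0.13); 26 of 32 libraries correlated best with a library of their own number in another group. Fits to the compared groups alone gave 41 for sugar in anoxic culture, 64 for atmosphere in sucrose, 4 for C. durum in anoxic glucose, 9 for P. gingivalis, and 55 and 113 for P. gingivalis cells and supernatant added to C. durum. DESeq2 within the libraries of 1 deposited table gave 1 for sugar in oxic and 35 in anoxic culture, 1 and 3 for C. durum in anoxic glucose and sucrose, and 26 and 53 for P. gingivalis added without and with C. durum. Atmosphere in sucrose gave 5 without the libraries numbered 1. Leaving out 1 library gave 0 to 7 tags for atmosphere in sucrose (7 without oxic sucrose numbered 2, 1 without that numbered 3), 0 to 6 for F. alocis (6 without its library numbered 3) and 0 to 5 for F. alocis added to C. durum (5 without its library numbered 3). Where a group kept a single library, that library was assumed to vary like the other groups. The other 232 planned values stayed at 0.

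For the averages, DESeq2 gave 73 tags for sugar, 113 for C. durum, 77 for F. alocis, 34 for P. gingivalis and 42 for F. alocis against P. gingivalis. The replicate block gave 77 for sugar (pairs r -0.06 to 0.65), 121 for C. durum, 60 for F. alocis and 41 for P. gingivalis, and moved no other count by over 1.5-fold (363 for atmosphere, 229 of the 273 among them; 26 for F. alocis against P. gingivalis). No filter on low counts, which tests more tags, gave 21 for sugar, 5 for C. durum and 6 for F. alocis. Fits to the compared groups alone gave 0 for F. alocis, 159 for P. gingivalis, 118 for its supernatant and 0 for F. alocis against P. gingivalis. Without the F. alocis libraries numbered 2 the C. durum, F. alocis and F. alocis against P. gingivalis averages gave 0 each. C. durum gave 61 without the libraries numbered 1 and 368 with a replicate block per background and number, and P. gingivalis 130 with DESeq2 on 1 table's libraries. With 1 library left out the ranges were 7 to 43 for sugar, 152 to 339 for atmosphere, 0 to 163 for C. durum, 0 to 46 for F. alocis, 0 to 3 for P. gingivalis and 0 to 41 for F. alocis against P. gingivalis. Sugar fell to 7 and 9 without anoxic sucrose numbered 2 and anoxic sucrose with C. durum numbered 3, to 21 and 9 without anoxic glucose numbered 2 and 3, to 12 without either anoxic glucose library with C. durum, and to 21 and 18 without oxic sucrose numbered 1, alone and with C. durum. Atmosphere fell to 153, 152, 158 and 158 without the anoxic libraries numbered 3 of sucrose, sucrose with C. durum, glucose and glucose with C. durum. C. durum gave 163 without oxic glucose with C. durum numbered 1, 5 and 50 without oxic glucose numbered 1 and 3, 4 and 34 without oxic sucrose numbered 2 and 3, 18 and 5 without oxic sucrose with C. durum numbered 1 and 3, 48 without F. alocis numbered 2, 62 without F. alocis with C. durum numbered 3 and 16 without P. gingivalis numbered 2. It gave 0 without anoxic sucrose numbered 2 (alone or with C. durum), anoxic glucose numbered 2, anoxic glucose with C. durum numbered 2 or 3, F. alocis, P. gingivalis or supernatant numbered 3, or any of these 3 with C. durum numbered 2. F. alocis gave 0 without either of its libraries numbered 2 or any 1 of the 4 libraries of anoxic glucose, alone or with C. durum, and 46 and 42 without its libraries numbered 3, alone and with C. durum. P. gingivalis gave 0 without anoxic glucose numbered 3, either anoxic glucose library with C. durum or its own library numbered 2, and 1 without anoxic glucose numbered 2. F. alocis against P. gingivalis gave 0 without either F. alocis library numbered 2 or any 1 of the 4 P. gingivalis libraries, and 39 and 41 without the F. alocis libraries numbered 3, alone and with C. durum. The cause was not tested for any of these shifts. For named tags no alternative turned a direction; 380 values stayed past the threshold and 165 did not, 140 of them with 1 library left out.

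For Count, the sugar difference of -3.18 on the log2 scale was -2.74 to -3.61 with 1 culture left out and stayed past the threshold, but not with the replicate block (-3.18, adjusted p = 0.0625), which 8 pairs could not pass. The atmosphere difference (0.27) ranged from -0.16 to 0.70 and turned to -0.035, -0.14 and -0.16 without oxic sucrose numbered 2, anoxic sucrose numbered 3 and anoxic sucrose with C. durum numbered 3, and the F. alocis difference (-0.081) ranged from -0.32 to 0.16 and turned to 0.16 without anoxic glucose numbered 3; neither had been called. Gene list tests and stable RNA removal were not run, as no tag matched a gene. Simulated 2-fold changes between oxic sugar groups were recovered in 7.67% of cases and for the sugar average in 54.3%; no simulation varied depth, so its part was not tested.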

Other observations

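The tests on neighbouring tags and on Count described here were chosen after the data were seen, and the tags outside the naming rule after their values were seen.

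Called tags of the atmosphere average lay beside each other along the tag numbers. Of the 273 tags, 176 had a called neighbour of the same direction, against a median of 38 and a highest of 75 in 10000 shuffles (permutation p = 1e-04, the smallest they can give), and 4 neighbouring pairs had opposite directions. The longest run held 11 tags. For the sugar average 19 of 32 tags had such a neighbour (highest of the shuffles 8), and for F. alocis 2 of 18 (permutation p = 0.08). Random placement along the tag numbers is thus argued against for the atmosphere average (176). Transcription units that change as a whole are a candidate explanation that could not be tested, because 0 tags were matched to a reference that gives strands. It is a hypothesis, and whether it would hold for counts of the opposite strand was not tested.

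Tags numbered between SSA_1362 and SSA_1369 recur among the named ones, not all in the same direction. SSA_1367 was higher in sucrose (by 1.94 on the log2 scale) while SSA_1369 was lower (by -1.11). SSA_1365 and SSA_1366 both rose with C. durum, and SSA_1362 and SSA_1367 both fell with F. alocis relative to P. gingivalis. SSA_1367 fell by 2.59 on the log2 scale with F. alocis, to between 428 and 3318 CPM. Whether these tags move jointly was not tested.

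SSA_2247 was the tag with the smallest p for C. durum in oxic glucose, without passing the threshold (log2 fold change -4.95, edgeR adjusted p = 1.00). In oxic glucose it had 42265 CPM alone and 1193 CPM with C. durum among libraries numbered 1, 7976 and 237 CPM among those numbered 2, but 123 and 178 CPM among those numbered 3. Oxic sucrose gave 17799 and 523 CPM, 9120 and 270 CPM, and 51.2 and 192 CPM in the same order. In anoxic culture it was higher with C. durum in several backgrounds without overlap, at 963 to 1180 against 147 to 654 CPM in sucrose, 411 to 506 against 100 to 204 CPM with F. alocis, 82.9 to 175 against 32.4 to 48.4 CPM with P. gingivalis, and 168 to 2734 against 61.7 to 132 CPM with supernatant. In anoxic glucose the libraries overlapped (431 and 2583 CPM with, 844 and 125 CPM without). SSA_2247 passed the threshold neither in anoxic glucose or sucrose nor in the C. durum average, and the other anoxic backgrounds were not tested one by one.

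Expression was also set against Count. Over 27 libraries edgeR called 0 tags whose level followed log2 Count (111 at an unadjusted p under 0.05). Over the 19 glucose libraries it called 7, all lower where Count was higher. With the replicate block it called 15, of which 13 were lower and 2 higher where Count was higher. A free shuffle of the Count values gave as many as 7 in 3 of 100 orders, the real one included, with 32 in the highest other. With the replicate block 1 of 100 orders gave as many as 15, with 14 in the highest other. These fits held no term for the group, and the shuffles did not keep libraries of a group together. Such libraries share their culture setting and are not independent, so these shares cannot decide whether chance gave the calls. Over the 12 glucose libraries without P. gingivalis cells or supernatant 0 tags were called (38 at an unadjusted p under 0.05), so the association is not seen apart from those cultures, with fewer libraries to show it.

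Some Count entries are identical. Both supernatant cultures with C. durum are listed at 12.95, and both anoxic sucrose cultures numbered 3 at 24.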
